A study of Homo sapiens with 6 samples.

How the data were processed

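Total RNA of 6 samples of DLD-1 subclones, 3 labelled DLD-1Δα-Cat and 3 labelled DLD-1α-Cat, was labelled with biotin and hybridised to Affymetrix oligonucleotide arrays with 54675 probe sets. The labels do not spell out Δα-Cat, and groups and replicate numbers were taken from the sample titles. The deposited values are on the log2 scale and were made by the authors with RMA (robust multi-array average) in Affymetrix Expression Console, per the submitters' processing notes; their versions are not given in the sources used here. RMA subtracts background, quantile-normalizes the arrays and summarises the probes of a set, which removes differences in overall brightness between arrays, so a change of all RNA together would not be seen. Array medians lay between 6.12 and 6.15. No scanner files or detection calls were used here, and values near the bottom of the scale cannot be told from background. Folds against a dim group are therefore folds on the log2 scale of RMA, not ratios of RNA copies.

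From these values, 62 control probe sets were left out. The platform annotation, dated 2016, gave 1 gene symbol for 41091 of the other 54613 probe sets, several for 1801 and did not list 11721, which are unnamed here. By gene ID, 41037 of the single-gene probe sets matched a RefSeq gene (assembly GRCh38.p14, used only for names and gene order) and 54 kept the annotation's symbol. No symbol changed. Each of the 19775 genes was represented by its brightest probe set, the one with the highest mean over the 6 arrays, and 10523 genes had more than 1. No filter was set on dim genes.

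Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, both groups in 1 model, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The median difference of all genes was -0.030. Lists of genes were fixed for 25 processes, pathways and cell types and tested with limma's camera at its preset correlation of 0.01, adjusted over the 25 lists. The lists share some members, so they are not independent. Chromosomes were tested in the same way, and the 20 tested genes on each side of CTNNA1 were described. The design, lists, rule for named genes and most alternatives were set before the data were examined. By that rule the text names CTNNA1 and 5 further catenin and cadherin genes (CTNND1 was in the rule and has no value), the 8 genes with the largest rise and the 8 with the largest fall whose arrays did not overlap, and up to 3 passing members of each list, or, where none passed, the most different member whose mean lay above the median of all tested genes. That gave 72 different genes. Of the 43 named and called genes with several probe sets, 12 had all of them past the threshold in the same direction, 31 had at least 1 that did not pass, and 0 had 1 past it in the other direction. In 5 of them (CLDN3, ASCL2, AXL, SQLE and ATF3) none passed when every probe set was tested. CTNNAL1, CTSD, TGFB1I1, PLK1 and BAMBI, each with a single probe set, did not pass in that fit either (limma adjusted p from 0.0510 to 0.0564). In all, 10 named genes lost the call there. Other list members were named to complete a count or an example, after their values had been seen.

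The titles number the replicates of both subclones alike. Deviations of same-numbered arrays from their group means correlated at 0.225, 0.376 and 0.122 over genes, each above the limit of 0.1, and each array correlated best with its own number. The numbers were therefore taken to pair the samples, from the data rather than from a stated design, and a fit with the number as a block was run as an alternative. Correlations between arrays were 0.9963 to 0.997 within DLD-1Δα-Cat, 0.9928 to 0.9962 within DLD-1α-Cat and 0.9835 to 0.9918 between the subclones. Replicate 1 of DLD-1α-Cat had the lowest array weight, 0.431.

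The other alternatives were quantile normalization of the deposited values, centring on the middle values, leaving out dim probe sets, the mean of a gene's probe sets, every probe set on its own, eBayes with trend and robust estimation, a fit without moderation, array weights and leaving out each array. For lists, camera with an estimated correlation, camera on ranks and fry were added. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. RNA quality was read from the 3' and 5' control probe sets of β-actin and GAPDH with exact permutation tests; a further control ratio is not reported here. For these 19775 genes, data were simulated for 3 against 3 arrays with 50 changed genes per size. Of genes changed by 0.5, 1, 2 and 4 on the log2 scale, 14%, 68%, 96% and 100% were recovered, and 9 of 148 calls were false. Most changes of 0.5 were thus missed there, and sizes between 0.5 and 1 were not simulated. A list of 40 independent genes moved by -0.3 was called, and 0 of 200 unmoved lists were. Members of real lists move together, with an estimated correlation of 0.543 in the proliferation list. The simulation therefore does not show how often camera at 0.01 calls unmoved lists of such genes. Figures were drawn with matplotlib.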

Results

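RNA of the human colon cancer cell line DLD-1 was measured on 6 oligonucleotide microarrays, 1 per sample. The samples were 2 subclones of the line, labelled DLD-1Δα-Cat (n = 3) and DLD-1α-Cat (n = 3). Both had been grown without treatment for 96 h inside a gel of type I collagen (1 mg/ml), the fibrous collagen of connective tissue. The arrays gave log2 intensities between 1.95 and 15.15, and 19775 genes were tested. The number of arrays, 3 per subclone, limits the precision of each value. Nothing in the labels says that the 3 arrays of a subclone came from separate cultures, so p-values measure only the spread between these samples, which may be technical. All differences are DLD-1Δα-Cat minus DLD-1α-Cat on the log2 scale, with the standard error (SE) and the Benjamini-Hochberg adjusted p of limma's moderated test.

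The comparison asked how the transcriptome of the subclone with the Δα-Cat label differed from that of the α-Cat subclone in a collagen gel. CTNNA1 encodes αE-catenin, which links the cadherin-catenin complex of adherens junctions to actin, and it served as a check of the labels. It stood at 11.23 ± 0.193 (SD, n = 3) in DLD-1Δα-Cat and at 12.75 ± 0.0324 (SD, n = 3) in DLD-1α-Cat, a difference of -1.52 (SE 0.119, adjusted p = 0.000838) or 2.87-fold. CTNNA1 RNA was thus lower but still among the brighter probe sets in DLD-1Δα-Cat, at percentile 89.8 of all probe sets. Of its 5 probe sets, 4 passed in the same direction, between -1.52 and -1.56, and the dimmest stood at -0.0056. With the β-actin 3' to 5' ratio as a covariate, an alternative chosen after seeing the data, its difference was -1.56 with adjusted p = 0.0667. The array does not measure αE-catenin protein. The neighbouring members of the complex did not pass: β-catenin (CTNNB1) differed by -0.068 (adjusted p = 0.699), plakoglobin (JUP) by -0.070 (adjusted p = 0.756) and E-cadherin (CDH1) by 0.044 (adjusted p = 0.846). The other α-catenins were dim in both subclones, and CTNNA2 differed by 0.13 (adjusted p = 0.601) and CTNNA3 by -0.59 (adjusted p = 0.202). For p120-catenin (CTNND1) every probe set was shared with another symbol, and it is not reported.

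**Figure D1:**
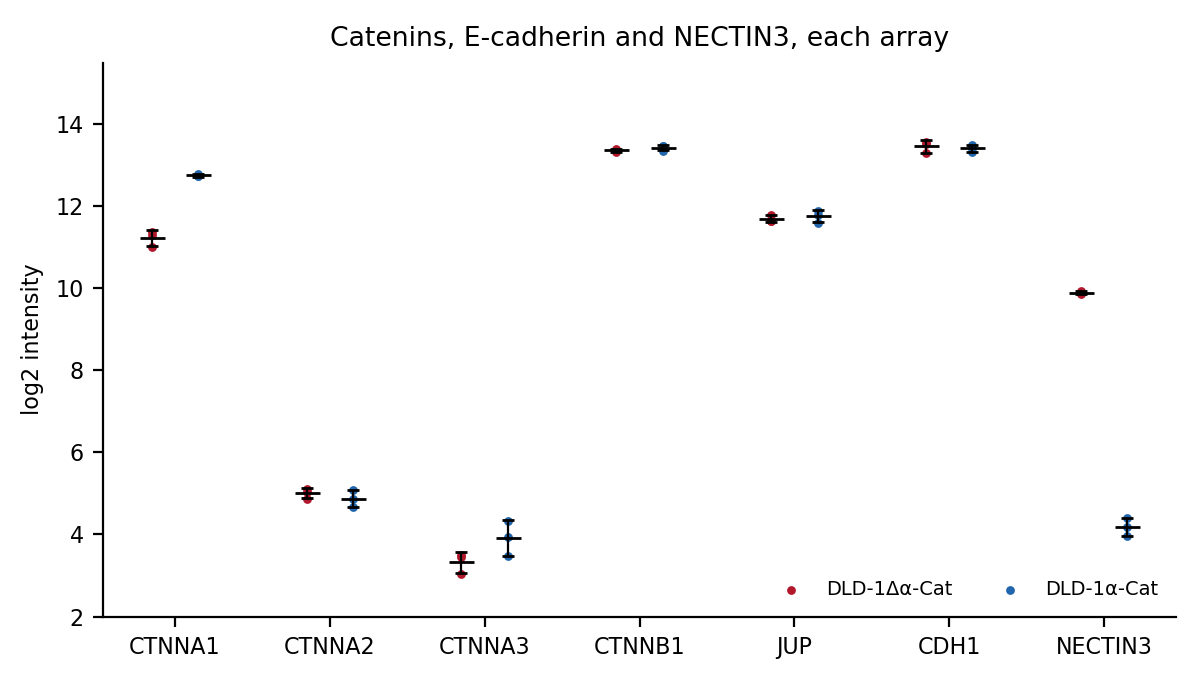
Log2 intensity (vertical axis) of the α-catenins, β-catenin, plakoglobin, E-cadherin and NECTIN3 on each array; points are arrays, bars the mean and SD of 3 arrays per subclone. CTNNA1 differs by -1.52 and NECTIN3 by 5.70, while CTNNB1, JUP and CDH1 overlap between the subclones.

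Across the transcriptome 760 genes were higher and 331 lower in DLD-1Δα-Cat, 5.52% of those tested. At least 2-fold changes were seen in 370 of the higher and 97 of the lower genes, and at least 4-fold changes in 71 and 18. The arrays of the subclones did not overlap for 5371 genes (27.2%, where chance gives 10%), and this held for all 1091 called genes. The largest rise was that of SH3BGRL, a small thioredoxin-like protein, from 4.73 ± 0.281 to 11.69 ± 0.173 (SD, n = 3 each). It was followed by RPS6KA6, a ribosomal S6 kinase (RSK4), at 5.86 (SE 0.115, adjusted p = 2.26e-06), and by NECTIN3, a nectin of adherens junctions, at 5.70 (SE 0.124, adjusted p = 2.38e-06). CALCA, which encodes calcitonin and CGRP, differed by 5.02, the kallikrein protease KLK7 by 5.01, the protease inhibitor A2M by 4.98, the intestinal keratin KRT20 by 4.89 and the RNA-binding protein ELAVL2 by 4.77. The deepest falls were those of the chromatin organizer SATB1 (-5.52, SE 0.256, adjusted p = 6.81e-05), ODAM (-5.29) and the helicase-like HLTF (-4.40). KLHL4 (-4.23), the choline transporter-like SLC44A4 (-3.57), ERICH5 (-3.53), the carboxypeptidase CPA6 (-3.27) and the GTPase RAB38 (-2.90) came next. Adjusted p of these 16 genes lay at or below 0.000550. KRT20, ODAM, HLTF and RAB38 rest on a single probe set, and the further probe sets of A2M, ELAVL2 and CPA6 did not pass. Those of KLHL4 and SLC44A4 passed, but only at -0.63 and -0.67. In most of the 16 genes the lower subclone lay in the dim range of the array, so such folds depend on the array's floor. Counts of calls depended on the arrays: without replicate 1, 2 or 3 of DLD-1Δα-Cat there were 462, 323 and 357 higher and 194, 119 and 136 lower genes, and without replicate 3 of DLD-1α-Cat 337 and 116. They also depended on the variance model, with 67 higher and 48 lower genes without moderation, 1150 and 564 with a variance trend and robust estimation, 549 lower genes with array weights, and 58 higher and 26 lower with the β-actin 3' to 5' ratio as a covariate, which was chosen after seeing the data.

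**Figure D2:**
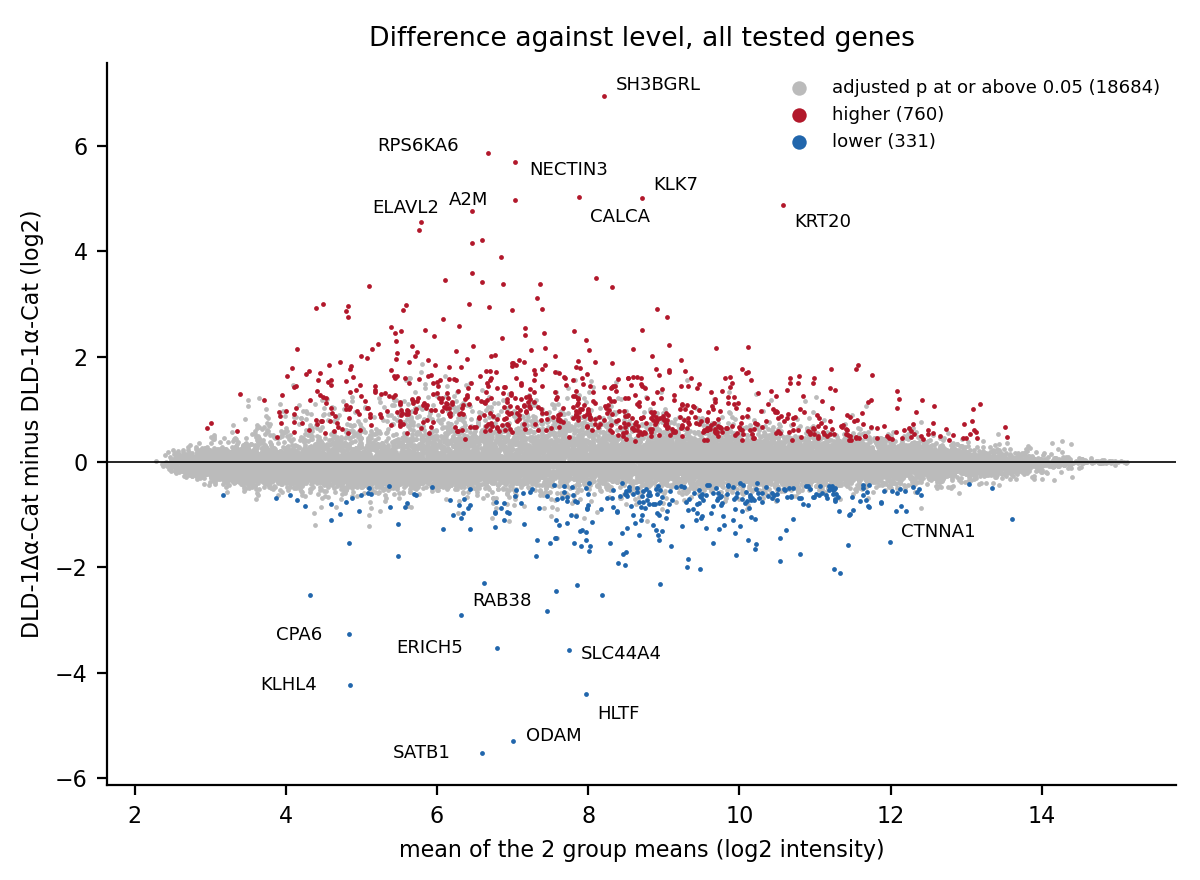
Difference between the subclones (vertical axis, log2) against the mean of both group means (horizontal axis, log2 intensity) for the 19775 tested genes. Red points are the 760 higher and blue points the 331 lower genes, grey points those that did not pass; labels mark CTNNA1 and the genes with the largest changes, from 6.96 (SH3BGRL) to -5.52 (SATB1).

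**Figure D3:**
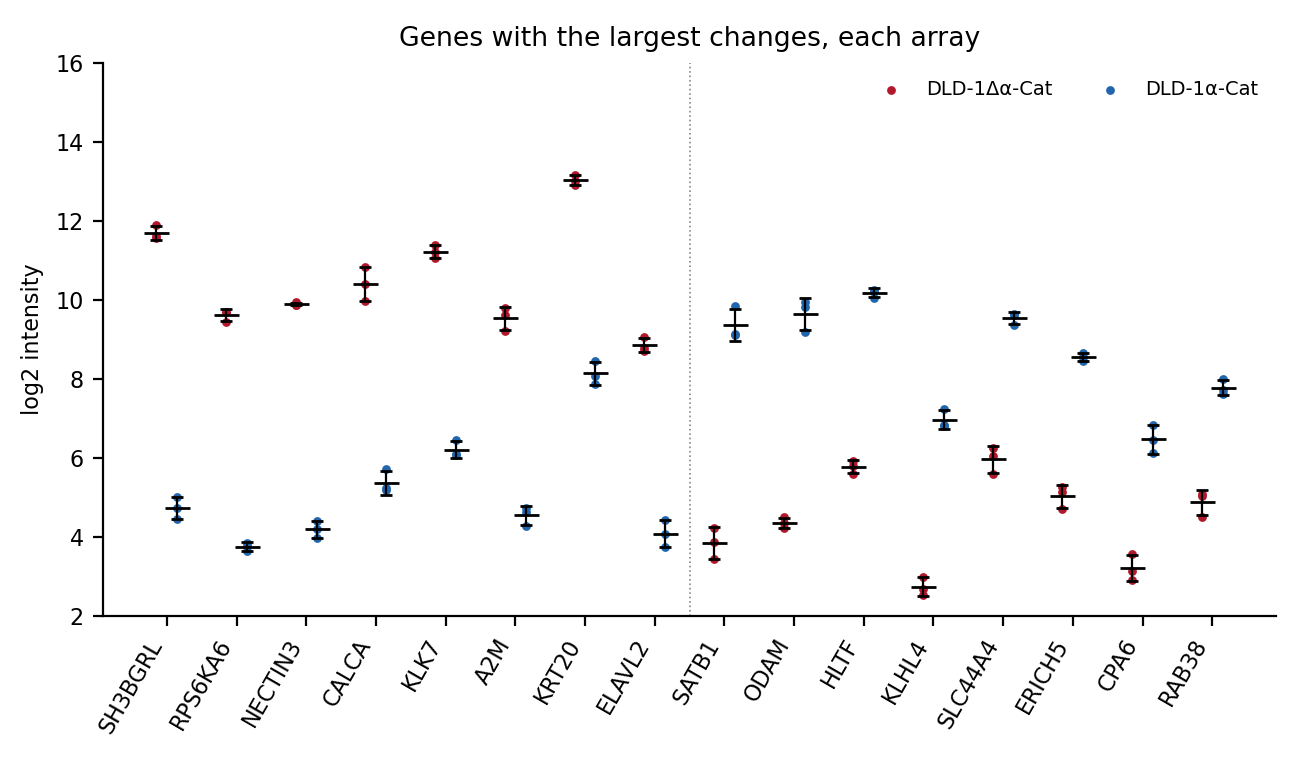
Log2 intensity (vertical axis) on each array of the 8 genes with the largest rise (left of the dotted line) and the 8 with the largest fall; points are arrays, bars the mean and SD of 3 arrays per subclone. For each gene the 3 arrays of one subclone lie clear of the 3 of the other.

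Cell junction genes changed singly rather than as groups. In the adherens junction list, 1 of 25 measured members rose (NECTIN3) and 2 fell, CTNNA1 and the α-catenin relative CTNNAL1 (-0.55, adjusted p = 0.0386). With p adjusted over the list alone, 2 were higher and 2 lower. Among 15 desmosome genes only plakophilin 2 (PKP2) fell, by 0.50 on the log2 scale (adjusted p = 0.0310), also the 1 call adjusted over the list alone. Of 34 tight junction and polarity genes, the pore-forming claudin CLDN2 (-1.01, adjusted p = 0.0219) and CLDN3 (-0.46, adjusted p = 0.0328) fell and the junctional adhesion molecule JAM2 rose (0.78, adjusted p = 0.0178), with the same counts adjusted over the list alone. None of the 3 lists shifted as a whole by camera (adjusted p = 0.722, 0.757 and 0.964). CTNNAL1, PKP2 and CLDN3 passed in 1 of the 6 runs that left out an array, CLDN2 in 2 and JAM2 in 4.

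The Wnt and YAP target lists did not shift. Among 24 Wnt/β-catenin targets the stem cell receptor LGR5 fell from 8.88 ± 0.0686 to 6.05 ± 0.485 (SD, n = 3 each; difference -2.83, adjusted p = 0.000889). FGF18 (1.05, adjusted p = 0.0131) and the stem cell transcription factor ASCL2 (0.46, adjusted p = 0.0463) rose. The counts adjusted over the list alone were 4 higher and 2 lower, and camera gave an adjusted p of 0.964. Of 21 YAP/TAZ-TEAD targets, GADD45A (0.65) and the receptor kinase AXL (0.58) rose (camera adjusted p = 0.698), or 3 higher and 0 lower adjusted over the list alone. ASCL2 and AXL passed in 0 of the 6 runs without an array, GADD45A in 3 and FGF18 in 5, and AXL did not pass with the replicate number as a block (adjusted p = 0.0565).

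Mesenchymal and epithelial genes gave no list-wide shift either. In the mesenchymal and EMT list, 4 of 29 members rose and 1 fell. The transcription factor ZEB1 differed by 1.96 (adjusted p = 0.0253) and PRRX1 by 1.73 (adjusted p = 0.000396), both from a dim level in DLD-1α-Cat, and S100A4, a calcium-binding protein of motile cells, by 1.11 (adjusted p = 0.00187). AXL rose and the TGF-β receptor TGFBR2 (-0.48, adjusted p = 0.0345) fell. Adjusted over the list alone 8 were higher and 2 lower, and camera gave an adjusted p of 0.366. ZEB1 passed on 1 of its 4 probe sets and in 2 of the 6 runs without an array, whereas PRRX1 and S100A4 passed in 6. Of 26 epithelial identity genes, OVOL1, a repressor of mesenchymal genes, rose (1.17, adjusted p = 0.0182), with the same count adjusted over the list alone, and the list gave an adjusted p of 0.15. OVOL1 passed in 3 of the 6 runs without an array.

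LAMA1, a laminin chain, rose by 1.04 (adjusted p = 0.0212), 1 of 31 laminin and matrix genes, also adjusted over the list alone. None of 23 integrins and collagen receptors passed, by either adjustment, and among members whose mean lay above the median of all tested genes the largest difference was that of CD44 (0.35, adjusted p = 0.0979). Among 35 genes of the list of matrix proteases and inhibitors 3 rose. These were the inhibitor TIMP3 (1.13, adjusted p = 0.00517), the serpin family member SERPINB5 (0.85, adjusted p = 0.00260) and the lysosomal protease CTSD (0.48, adjusted p = 0.0350). There were 3 higher and 1 lower adjusted over the list alone. Of 32 actin and SRF/MRTF genes, the focal adhesion protein TGFB1I1 rose (0.75, adjusted p = 0.0391) and TAGLN2, a transgelin, fell (-0.60, adjusted p = 0.0319), against 2 higher and 3 lower adjusted over the list alone. Camera gave adjusted p = 0.757, 0.485, 0.882 and 0.964 for these 4 lists. LAMA1 passed in 3 of the 6 runs without an array, TGFB1I1 in 2, TAGLN2 in 1 and CTSD in 0. With the replicate number as a block LAMA1 did not pass (adjusted p = 0.0510).

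Differentiation genes of the intestine went in both directions. In the absorptive enterocyte and colonocyte list 2 of 31 members rose, KRT20 from 8.13 ± 0.289 to 13.02 ± 0.126 (SD, n = 3 each) and the adhesion molecule CEACAM6 (2.54, adjusted p = 0.0113). The brush border peptidase DPP4 (-1.60, adjusted p = 0.0105), the carbonic anhydrase CA2 (-1.39, adjusted p = 0.00159) and the intestinal transcription factor CDX1 (-1.09, adjusted p = 0.00117) fell. The goblet and secretory list had 4 of 35 members higher, AGR3 (2.51, adjusted p = 0.00453), lysozyme (LYZ, 1.54, adjusted p = 0.0167), the mucin MUC1 (1.12, adjusted p = 0.0306) and ITLN1 (1.09, adjusted p = 0.0416). ZG16, a goblet cell lectin, was lower (-0.97, adjusted p = 0.00785). For the 2 lists the counts adjusted over the list alone were 2 higher and 3 lower, and 7 higher and 1 lower. Camera gave adjusted p = 0.251 and 0.722. CEACAM6 and DPP4 passed in 5, LYZ in 3 and MUC1 in 1 of the 6 runs without an array.

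All 43 measured proliferation genes lay below 0, with differences from -0.83 to -0.11. The median difference was -0.33, and 7 of them passed on their own: the ubiquitin-conjugating enzyme UBE2C (-0.83, adjusted p = 0.0180), the mitotic kinases PLK1 (-0.68, adjusted p = 0.0388) and BUB1 (-0.68, adjusted p = 0.0269), CDC20, CCNB1, KIF20A and KIF2C. Adjusted over the list alone 14 were lower and 0 higher. The list's camera adjusted p was 5.19e-12. It was 0.866 with the correlation between members estimated from the arrays (0.543), and fry gave an adjusted p of 0.0956. The mean of the 43 genes was 11.04 ± 0.132 against 11.43 ± 0.117 (SD, n = 3 each), and the exact permutation test gave p = 0.1, two-sided, the smallest that 3 against 3 arrays allow. A sign of RNA quality moved with the same split: the log2 ratio of the 3' to the 5' control probe sets of β-actin was 5.20 ± 0.159 in DLD-1Δα-Cat and 4.69 ± 0.291 in DLD-1α-Cat (SD, n = 3 each; exact permutation p = 0.1). It lay between 4.36 and 5.38 on all 6 arrays, so the 5' β-actin probe set was far dimmer than the 3' one in both subclones. The GAPDH ratio lay between 0.51 and 0.82. UBE2C passed in 3, BUB1 in 2 and PLK1 in 1 of the 6 runs without an array.

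In the list of the unfolded protein and integrated stress response, 4 of 25 members rose and 0 fell, the same counts as adjusted over the list alone. DDIT3, the transcription factor CHOP, differed by 1.38 (SE 0.101, adjusted p = 0.000721), the lipoprotein receptor VLDLR by 1.09 (adjusted p = 0.00163), ATF3 by 0.66 (adjusted p = 0.0403) and HERPUD1, of the degradation machinery of the endoplasmic reticulum, by 0.45 (adjusted p = 0.0457). The list's median was 0.18 and its camera adjusted p 0.0178. That p was 0.866 with an estimated correlation, 0.0512 with the replicate number as a block and 0.0504 without replicate 1 of DLD-1α-Cat. It was also above the threshold with fry (0.0812), on ranks (0.0846), without dim probe sets (0.0967), with every probe set tested (0.219) and with the mean of probe sets (0.246). ATF3 passed in 1 of the 6 runs without an array, DDIT3 and VLDLR in 6.

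Immune and signalling lists held a few called genes each. IFI35 fell (-1.78, adjusted p = 0.00328) among 40 interferon response genes, while RSAD2 (1.13), OAS2 (1.05), SAMD9 (0.73) and UBE2L6 (0.53) rose. OAS2 passed on 1 of its 3 probe sets, and the others, at -0.14 and -0.33, did not pass. The antigen presentation genes HLA-DMB (1.01, adjusted p = 0.00837) and HLA-B (0.54, adjusted p = 0.0270) rose, 2 of 26. Of 32 NF-κB targets and cytokines the iron-binding LCN2 (2.17, adjusted p = 0.00446) and the prostaglandin synthase PTGS2 (1.20, adjusted p = 0.00664) rose, and the chemokine CXCL5 (-1.88, adjusted p = 0.00134) and the cytokine IL18 (-0.81) fell. Of 25 MAPK/ERK and EGFR ligand genes ETV1 (-0.65) and IER3 (-0.49) fell. Adjusted over the list alone, the higher and lower counts of these 4 lists were 8 and 1, 2 and 0, 3 and 4, and 2 and 5. Among 29 TGF-β, BMP and SMAD targets the cell cycle inhibitor CDKN2B (1.34, adjusted p = 0.00107), ID3 (0.78) and the pseudoreceptor BAMBI (0.49) rose and TGFBR2 fell, or 4 higher and 2 lower adjusted over the list alone. None of the 5 lists passed by camera, with adjusted p = 0.224, 0.757, 0.698, 0.698 and 0.757. HLA-B and IER3 passed in 1, BAMBI in 0, and RSAD2, OAS2 and ETV1 in 3 of the 6 runs without an array.

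Among 33 hypoxia and glycolysis genes 5 rose and 0 fell. These were the oxygen sensor EGLN3 (1.19, SE 0.0902, adjusted p = 0.000792), enolase 2 (ENO2, 0.86), the glucose transporter SLC2A3 (0.85), VEGFA (0.53) and NDRG1 (0.49). The median of the list was -0.028, its camera adjusted p 0.757, and adjusted over the list alone 7 were higher and 4 lower. Of 18 genes of cholesterol biosynthesis SQLE fell (-0.45, adjusted p = 0.0342), 1 lower also adjusted over the list alone, and the list gave an adjusted p of 0.15. ENO2 passed in 2, SLC2A3 in 4 and SQLE in 1 of the 6 runs without an array. Markers of other cell types did not shift as lists. None rose or fell among 2 of them: 0 of 14 fibroblast and 0 of 12 endothelial markers passed by either adjustment. Of 14 leukocyte markers LYZ rose and CD14 fell (-1.17, adjusted p = 0.00517), against 1 higher and 3 lower adjusted over the list alone. The 3 lists had medians of -0.10, -0.20 and -0.17 and camera adjusted p = 0.698, 0.15 and 0.202. The mean and median differences had opposite signs in 9 of the 25 lists, and the camera direction opposed the median in 8, none of them called.

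**Figure D4:**
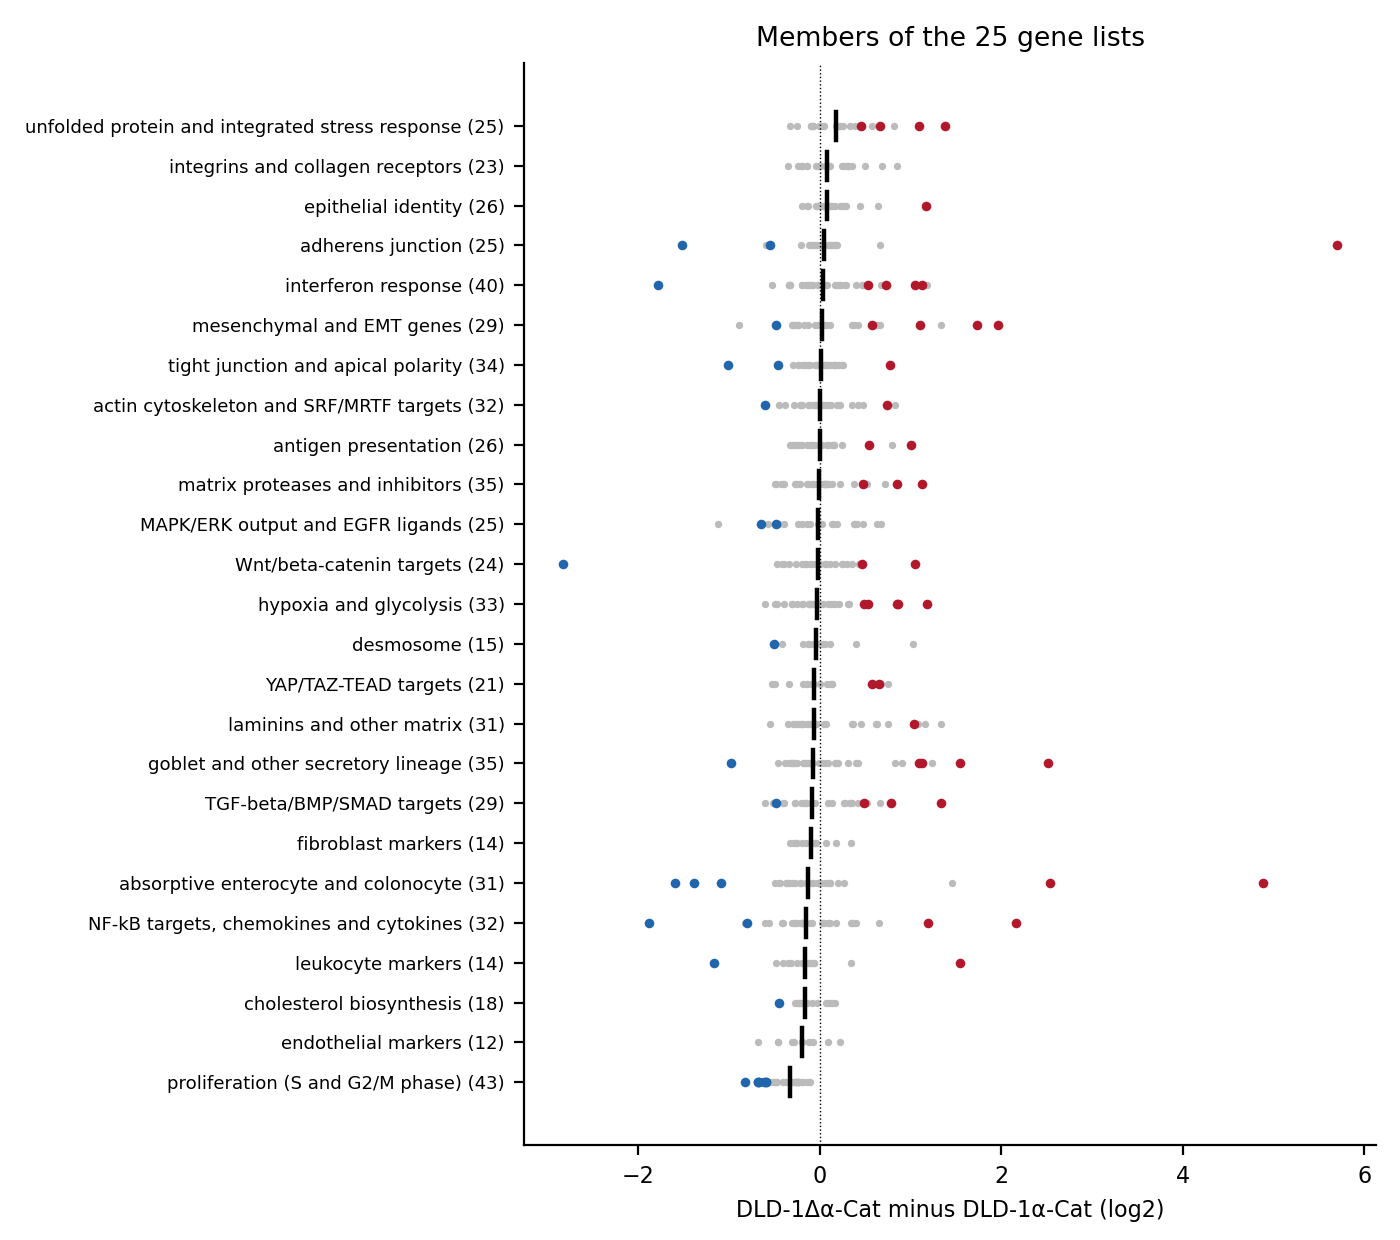
Difference between the subclones (horizontal axis, log2) of each measured member of the 25 gene lists, with the number of members in parentheses. Points in red and blue passed as higher and lower, grey points did not pass, and black bars are list medians; the proliferation list lies wholly below 0, with a median of -0.33.

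No chromosome shifted as a whole. By camera 0 of 25 chromosomes passed, 0 at an unadjusted p under 0.05, and 0 passed with an estimated correlation. Chromosome medians lay between -0.065 and 0.0071. The 40 tested genes nearest to CTNNA1 had a median of 0.052 and a range of -0.74 to 1.17, and 1 of them was lower and 0 higher.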

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

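The tests of the actin ratio, matched lists, neighbouring genes, further probe sets and single arrays, the fits of the proliferation list by pairs, and the count over splits of called genes and of chromosomes, were chosen or worded after the results had been seen. The split counts of 2-fold genes and of lists were not.

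Probe sets that carry no single gene name were outside the comparison of genes, yet 164 of 13522 were higher and 38 lower in DLD-1Δα-Cat in a fit over all probe sets. At least 2-fold changes were seen in 96 and 12. The largest rises, 5.41 (adjusted p = 0.00201) and 5.40 (adjusted p = 0.000250), were of the size seen in the 8 named genes that rose most, and the deepest falls were -1.91 and -1.53.

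The number of called genes was compared with the other splits of the 6 arrays. The 10 splits are too few for a share under 0.05. Every other split also puts arrays of both subclones in each group. The difference between the subclones then adds to the spread within groups, so few called genes could be expected there beforehand. Their counts are therefore not a level of calls that chance gives. The real split gave 1091 calls and 467 of at least 2-fold, and the highest other split gave 0 and 0, so 1 of the 10 reached each real count. Among the 4 splits that part all 3 replicate pairs the highest other count was 0 as well. List calls did not set the real split apart: 7 of the 10 splits called at least as many lists as the real 2, with up to 7 in another split and up to 3 among those that part all pairs. For chromosomes the real count was 0, which any split reaches, so this comparison cannot set the splits apart. The highest other count was 1.

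The lower level of the proliferation genes was weighed against RNA quality, brightness and single arrays. Their brightness is argued against by the list's median, which lay at percentile 0 of 10000 random lists matched on mean level. A single array is argued against by the median with each array left out, which was at most -0.26. RNA quality stays open, since the β-actin 3' to 5' ratio differed by 0.52 between the subclones, and with the ratio in the fit the difference of the list's mean went from -0.39 (95% interval -0.67 to -0.11) to -0.14 (-0.39 to 0.11, upper end 0.113, with 3 residual degrees of freedom). Those fits leave out the pairing by replicate number. Within the 3 pairs the list's mean differed by -0.32, -0.43 and -0.42 and the ratio by 0.34, 0.49 and 0.72, so both moved one way in each pair. With the number as a block the difference was -0.39 (95% interval -0.54 to -0.24), and with block and ratio -0.27 (-1.77 to 1.23, with 1 residual degree of freedom), which is too wide to decide. The GAPDH ratio differed by 0.093 (exact permutation p = 0.4), and slower growth of the DLD-1Δα-Cat subclone in collagen is the biological alternative, which the arrays do not measure.

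Changes of at least 16-fold were seen in 16 genes. A fault of a single probe set is argued against for 8 of them, which had a further probe set past the threshold and changed at least 4-fold in the same direction, by 2.74 (NRIP1) to 7.86 (SH3BGRL) in size. For the other 8 it stays open. HLTF, KRT20, ODAM and ZNF432 had no further probe set, that of KLHL4 passed at -0.63 only, and those of A2M (-0.20, adjusted p = 0.497), AUTS2 (0.20 and -0.32) and ELAVL2 (1.32, adjusted p = 0.0533) did not pass. Gain or loss of a segment was read from the nearest neighbours above the median level. In 12 of the genes no such neighbour was called in the same direction. The 12 were picked by this, which in part holds their neighbours' values low. The median over the 12 genes of their neighbours' median signed difference was 0.0365, and the highest of these medians was 0.27. Over their single neighbours the upper quartile was 0.15, where 3 copies against 2 would give 0.58 if RNA followed DNA. ZNF616 near ZNF432 lay above that, at 0.83. A2M-AS1 (1.74), named as the antisense of A2M, and LINC00612 (0.85) lie next to each other on chromosome 12. Both were called higher, as A2M was, but neither was among the neighbours read for A2M. A change that A2M shares with these 2 genes stays open. Within the limit of how the 12 were picked, these values argue against a segment that moves most of these neighbours by 0.58 or more. They do not argue against a smaller segment or a smaller shift in RNA. For 2 genes gain or loss of a segment stays open, as CDKN2B (1.34) near ELAVL2 and POF1B (-0.92) near KLHL4 changed in the same direction as these. Their other neighbours were not called in that direction. These were MTAP (-0.18), CAAP1 (0.10) and PLAA (-0.19) near ELAVL2, and ZNF711 (0.56), DIAPH2 (0.79) and TSPAN6 (-0.049) near KLHL4. The remaining SH3BGRL and RPS6KA6 lie close together on chromosome X with HMGN5 (3.34) next to SH3BGRL. Of the 5 tested genes in that stretch only these 2 were above the median level in DLD-1Δα-Cat, so no independent gene was left to test loss of the stretch in DLD-1α-Cat, and neither loss nor silencing was tested. Each label names 1 subclone, so differences that arose with α-catenin and differences that the subclones carried otherwise were not separated by this design.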

How the results depend on the processing

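The run with the actin ratio as a covariate and the run without both arrays numbered 1 were chosen after seeing the data. The sign of all 1091 called genes was kept with renewed quantile normalization, centring and the actin covariate, and that of the 891 left for comparison without dim probe sets. With the mean of probe sets 4 turned, 0 of them past the threshold. No called gene's arrays overlap between the subclones, so array weights and left-out arrays cannot turn its sign, and the block leaves each difference as it is. Neither called list changed direction in the runs made for lists, nor any named gene that passed in the runs that could turn its sign. With each array left out, higher genes numbered 323 to 854, lower genes 116 to 348, lists 1 to 3, and the stress response list had adjusted p = 0.00286 to 0.0504; without both arrays numbered 1 there were 391 and 152 genes and 1 list (stress response adjusted p = 0.0529). Leaving out arrays takes degrees of freedom from the test. Higher and lower genes numbered 1150 and 564 with a variance trend and robust estimation, and 67 and 48 without moderation, of which 46 and 28 were at least 2-fold. With array weights 549 were lower. With the actin covariate, 58 and 26 genes passed, all of at least 2-fold (58 and 26), and CTNNA1 went from -1.52 to -1.56 with adjusted p = 0.0667; this fit has 1 degree of freedom less and a covariate that differs between the subclones. The replicate block, which treats samples of the same number as pairs, gave 1012 higher and 449 lower genes, CTNNA1 at -1.52 and 0 chromosomes. The block gave 1 list, since the stress response list had adjusted p = 0.0512. It kept 672 of the 760 higher and 286 of the 331 lower genes, ended the calls of 2 named genes, AXL (0.58, adjusted p = 0.0565) and LAMA1 (1.04, adjusted p = 0.0510), and changed no other call reported for lists or chromosomes. Called lists numbered 1 without dim probe sets (stress response 0.0967), 1 with the mean of probe sets (0.246), 1 on ranks (0.0846), 0 with fry (0.0812, proliferation 0.0956) and 0 with an estimated correlation (0.866 for both). Tested by every probe set, the stress response list was lost (0.219), and 3 lists passed. The proliferation list had adjusted p at or below 0.0202 in all other runs. The causes of these changes were not tested beyond what is said here. Camera has no option without moderation, so lists were not run that way. Of 65 further named genes that passed, 33 passed with each array left out in turn, and 18 in all 17 runs that refit the genes or in those that kept their probe set; 264 of 1195 single outcomes of named genes lost the call and 1 gained it (CD44). For uncalled lists, 3 outcomes gained a call. Chromosome calls stayed at 0 in the runs that tested them: renewed quantile normalization, no dim probe sets, the replicate block, each left-out array and the estimated correlation. Signal over background sets the limit for dim genes, of which no detection calls were used here.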

Other observations

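The family test, the ZNF counts without an array, with the replicate block and with the actin ratio, and the shuffles without histone and zinc finger pairs were chosen after the results had been seen, and the other shuffles and matched draws were worded before their outcome for patterns already noticed. Genes whose symbols open with ZNF, most of which encode zinc finger proteins, were more often higher in DLD-1Δα-Cat than other genes: 42 of 502 rose (8.37%, against 3.84% of all genes) and 3 fell. Of the 42, 38 are protein-coding, 2 are long noncoding RNAs and 2 are transcribed pseudogenes. This was the 1 of 516 tests over 258 gene families, sorted by the letters that open the symbol, that passed (Fisher's exact test, one-sided, adjusted p = 0.00109). The largest rises were those of ZNF432 (4.55), ZNF431 (2.35), ZNF141 (1.68) and the pseudogene ZNF137P (1.63), and ZNF572 (-2.53) fell. The counts were 44 and 3 with renewed quantile normalization and 42 and 3 with centring on the middle values, which move little, and 53 and 3 with the replicate block. With an array left out 14 to 43 rose, with unadjusted one-sided Fisher p from 1.62e-05 to 0.082, the last without replicate 1 of DLD-1Δα-Cat. Without its replicates 2 and 3 that p was 0.0371 and 0.04, and without replicate 3 of DLD-1α-Cat 0.0127. With all arrays the unadjusted p was 2.11e-06. The left-out values are all larger. The 0.082 cannot pass over the 516 tests, since adjustment never lowers a p, and whether the others would pass was not tested. On chromosome 19, 27 of 234 ZNF genes rose (11.5%), against 26 of 1086 other genes (2.39%). Sets matched on mean level held 23.4 higher genes on average and at most 43 in 10000 draws (permutation p = 4e-04, one-sided). The count was thus above what the level of these genes gave in most draws. The draws and Fisher's test take genes as independent, and the family was picked by its count, so these p-values may be too small. RNA quality stays open, since the β-actin 3' to 5' ratio differed between the subclones. With that ratio in the fit 1 ZNF gene was among the 58 higher genes (Fisher p = 0.775, one-sided), too few calls to decide, and the median difference of the ZNF genes went from 0.12 to 0.17 while that of all genes went from -0.030 to 0.0082.

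Cytochrome P450 genes came next, with 9 of 55 higher (adjusted p = 0.0586), among them CYP4B1 (2.95), CYP4X1 (2.88) and CYP4F3 (2.10), and then the HOXC genes, with 4 of 10 higher (adjusted p = 0.0649): HOXC4 (2.49), HOXC6 (1.69), HOXC10 (1.04) and HOXC9 (1.00). Neither passed.

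Called genes lay next to each other in gene order more often than calls shuffled over genes of like level. There were 70 neighbouring pairs that changed in the same direction, against 36.9 on average and at most 61 in 10000 shuffles (permutation p = 1e-04, one-sided, the smallest they can give). Without pairs that overlap or share the first 3 letters of their symbols 43 remained, against 28.4 on average (permutation p = 0.0048). These still held relatives such as H2BC4 with H2AC6 and ZNF211 with ZSCAN4, and 41 remained, against 28.2 on average, without histone and zinc finger pairs as well (permutation p = 0.013). Other relatives that differ in symbol were not removed. Among the neighbours that remained were CHRNA1 (-1.74) and CHN1 (-1.07), LRP2 (1.74), BBS5 (2.30) and KLHL41 (2.14), and SDR42E1 (2.71) and HSD17B2 (0.92). Regional differences in chromatin or copy number between the subclones are a hypothesis that these values may fit (permutation p = 0.013 without histone and zinc finger pairs). Neither was measured. Whole chromosomes and the neighbours of genes changed at least 16-fold were read from RNA only, as given above. For the pairs found here neither cause was tested.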
